A study of Homo sapiens with 6 samples.

How the data were processed

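Gene expression was measured in a hepatoma cell line on Agilent 1-colour microarrays, per the series' design text and the labels. The design text and the growth and treatment protocols name the line PLC/PRF/5, the name used here, while the sample titles, source names and characteristics spell it PLC/PFR/5. Wells of a 6-well plate were transfected with 7 nmol of a small interfering RNA against PPT1 (si-PPT1) or with a control siRNA (siRNA-NC), and total RNA was taken 48 h later. All 3 si-PPT1 titles name the siRNA si-PPT1-1, so effects of PPT1 loss cannot be told from other effects of that siRNA. Each group held 3 arrays. The labels number them 1 to 3 and do not say whether they came from separate cultures, so that p-values here measure only the spread between these samples, which may be technical. Slide and scan date are not given in the sources used here, so array batches could not be examined.

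The only file was the value table of the series, with 58341 rows (1 per probe), 6 array columns and 0 missing values. The deposited values are log2 normalized intensities: per the series' design text, the authors extracted the scans with Feature Extraction, quantile normalized them and processed them further with the R package limma, and per the submitters' processing notes the Feature Extraction version was 10.7. Background correction, probe filters and the averaging of repeated spots are not given in the sources used here. The values ran from 1.09 to 17.8 with nearly equal quartiles on all arrays, were not centred per probe, and needed no further normalization or log transformation. Quantile normalization gives every array nearly the same distribution of values, so that a change of total mRNA common to most genes cannot be seen in them. No detection flags, background values or spot intensities were used here, so a level near the bottom of the scale can be noise.

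The file gives probe names only. Of the 58201 probes for genes, 0 names matched an identifier in the reference gene table used here (assembly GRCh38.p14), and no table pairing these probes with genes was used. Genes are therefore not named. The planned check of PPT1 itself, the planned counts per gene and the planned tests of 38 gene lists (fixed before the data were examined) were not run, and counts of probes stand in their place. A gene can have several probes, so a count of probes is not a count of genes.

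The 140 control rows were left out of all tests. They comprised 10 probes named (+)E1A for Agilent's spike-in transcripts, 96 named ERCC, 13 named ETG, 18 named DCP and 3 others. Each of the 58201 remaining probes was fitted with limma 3.58.1 under R 4.3.3 (lmFit and eBayes with a constant prior, group as the only term, 4 residual degrees of freedom). A probe was called when its two-sided p, adjusted over all 58201 probes by Benjamini-Hochberg, was under 0.05. Differences are si-PPT1 minus siRNA-NC on the log2 scale, without a pseudocount. The design text's own criterion, Student's t-test at p under 0.05 with a fold above 2, was run on the same values as the methods' t-test. Probes singled out by name followed a rule set before the data were examined: among called probes whose 3 si-PPT1 values did not overlap the 3 siRNA-NC values and whose mean lay above the median of all probe means (2.26), those with the largest rise and fall. The planned 10 per direction were reduced to 2, since the probes carry no gene names. Where a named probe lay below the 95th percentile of the ERCC and ETG probes of an array, that limit took the place of its value for a bound on the fold, a step added after seeing the data. The rule's further part, 4 members per gene list, needed gene names.

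The fit was tested on simulated data: normal values with each of the 58201 probes' own mean and residual SD, in which 200 probes brighter than log2 7 were shifted. Of the 100 probes shifted by 1 log2 unit, 74 were called, and of the 100 shifted by 2 log2 units, 93. Among all unshifted probes 14 were called. The simulated values were independent between probes, with the same SD in both groups. The 200 shifted probes were far fewer than the 3105 called in the data, and the adjusted p depends on how many probes change. The recovery therefore does not cover dimmer probes or the number of changes in the data. Neither result covers unequal SDs of the groups or deviations that many probes of an array share.

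Alternatives set before the data were examined were a second quantile normalization, centring on the median or the 75th percentile, filters at the median and the 25th percentile of the probe means, a variance prior with an intensity trend, array weights, the methods' t-test, the replicate number as a block, and leaving out each array. Alternatives added after seeing the data were centring on the spike-in probes, filters by the array's own ERCC and ETG probes or at log2 7, and leaving out siRNA-NC arrays 2 and 3 together. Arrays give no counting depth. Their number, 3 per group, limits the precision.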

Results

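The series asked which transcripts lie downstream of PPT1 in hepatocellular carcinoma. PPT1 encodes palmitoyl-protein thioesterase 1, a lysosomal enzyme that removes palmitate from proteins. PLC/PRF/5 (PLC/PFR/5 in the sample titles), an established human hepatoma cell line, was transfected with an siRNA against PPT1 (si-PPT1, 3 arrays) or with a control siRNA (siRNA-NC, 3 arrays), and RNA was profiled 48 h later. Each array gave a log2 normalized intensity for 58201 probes for genes. Array medians lay between 2.37 and 2.39. Between 16262 (27.9%, siRNA-NC replicate 3) and 30940 probes (53.2%, siRNA-NC replicate 1) exceeded the 95th percentile of the ERCC and ETG control probes of the same array. The probes could not be paired with genes here, so the level of PPT1 itself was not analysed and the groups stand as labelled.

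Among the 12250 bright probes, those with a mean above log2 7, the arrays separated by group. Pearson's r across these probes was 0.996 to 0.998 between si-PPT1 arrays, 0.988 to 0.993 between siRNA-NC arrays and 0.978 to 0.985 between arrays of different groups. Probes are not independent replicates, and these values describe the arrays only. The first principal component held 63.1% of the variance of the bright probes. On it the si-PPT1 arrays scored 18.4 to 19.2 and the siRNA-NC arrays -20.8 to -15.5. Over all 58201 probes the si-PPT1 arrays stayed closer to each other (r 0.9895 to 0.9919) than to any siRNA-NC array (0.9536 to 0.9893). The siRNA-NC arrays did not group there, with 0.9556 to 0.9829 between them.

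After si-PPT1, 3105 probes differed from the control siRNA, 5.34% of those tested (limma, Benjamini-Hochberg adjusted p under 0.05, 3 arrays per group). Of these, 1609 rose and 1496 fell. Most changes were modest: the median rise was 0.58 log2 units (1.49-fold), the median fall was -0.54 log2 units (1.46-fold), and 2629 called probes (84.7%) changed less than 2-fold. At least 2-fold, 289 probes rose and 187 fell. At least 4-fold, 26 rose and 14 fell. Many of the larger rises involve levels near background. On all 6 arrays, 88 of the 289 and 3 of the 26 exceeded the 95th percentile of the ERCC and ETG control probes. So did 155 of the 187 and 9 of the 14 falls. That limit was log2 2.12 to 3.23 on si-PPT1 arrays and 2.10, 4.84 and 5.73 on siRNA-NC replicates 1, 2 and 3. Rises have their low values on siRNA-NC arrays and falls on si-PPT1 arrays, so these shares of rises and falls are not comparable. The groups did not overlap in any called probe. Over all probes they did not overlap in 26.5%. Without ties, the mean of this share over the 10 splits of the arrays into 3 and 3 is 10%. Deviations that many probes of an array share can move a single split away from that mean, so this is no test. The smallest adjusted p was 0.00323.

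The number called depended on the settings of the fit and on single arrays. With all 6 arrays, array weights gave 5386 calls, the filter at the 25th percentile 1797, and the replicate number as a block 0. The block leaves fewer residual degrees of freedom, and all 3105 probes kept an unadjusted limma p under 0.05 with it. Of 19 alternatives in all, 10 kept the number called within 1.5 times of the reported one, 7 gave fewer and 2 gave more. The number called was 1039, 746 and 727 without si-PPT1 replicates 1, 2 and 3, and 452 without siRNA-NC replicate 2. Without siRNA-NC replicate 1 the number that fell was 2715, and 674 rose at least 2-fold. In each of the 6 fits without 1 array, all 3105 probes kept an unadjusted p under 0.05, though these fits share most of their arrays with the fit to all 6. They also kept their direction, which is no test. Groups that do not overlap in a probe cannot change order when an array is left out. With arrays centred on the spike-in probes, an alternative added after seeing the data, the median of all probes shifted to 0.14 log2 units, and 2662 probes rose while 696 fell (79.3% higher, against 51.8%). The balance of rises and falls is therefore relative to the deposited normalization. With siRNA-NC arrays 2 and 3 both left out, 1 control array remains, which gives no spread between controls. Calls from that fit are therefore not read, and the 3105 calls could not be checked without these arrays. The direction of all 3105 could not change in that fit either, since the groups did not overlap in them.

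**Figure D1:**
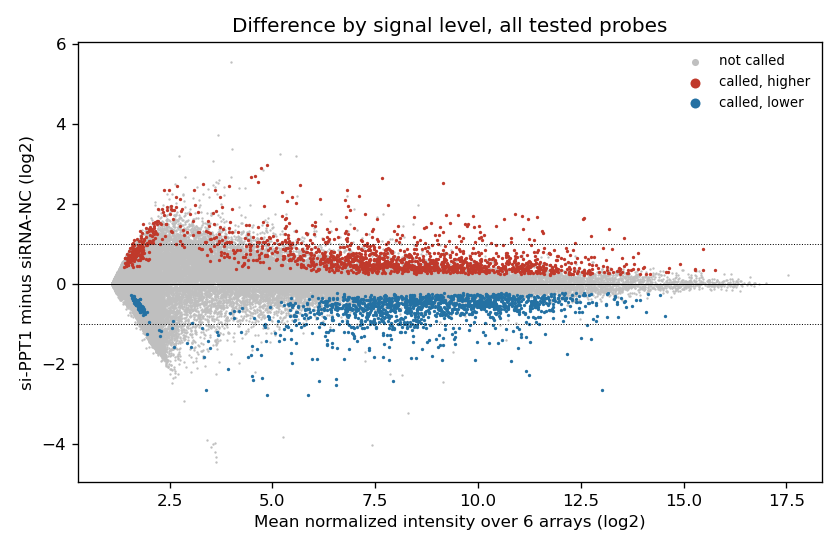
Difference between si-PPT1 and siRNA-NC (log2) against the mean normalized intensity over the 6 arrays (log2), 1 point per tested probe. Red points are the 1609 probes called higher, blue points the 1496 called lower, grey points the rest, and dotted lines mark a 2-fold change; calls lie mostly at bright levels, and the largest differences are grey.

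The rule for named probes ranked A_23_P324754 first among the rises. Its log2 intensity was 3.37 ± 0.27 (SD, n = 3) after siRNA-NC and 6.34 ± 0.14 (SD, n = 3) after si-PPT1 (limma adjusted p = 0.00445). A_23_P106194 was second, from 3.27 ± 0.49 to 6.16 ± 0.09 (SD, n = 3 each; limma adjusted p = 0.0106). On siRNA-NC replicates 2 and 3 both probes lay below the 95th percentile of the ERCC and ETG control probes (4.84 and 5.73), so their rises are given as bounds. With that limit in place of the lower values, the group means differed at least 3.19-fold and 2.83-fold. These bounds depend on the control arrays: they were 2.08-fold and 1.83-fold without siRNA-NC replicate 1, the only control array on which the probes exceeded the limit, and 4.61-fold and 4.11-fold without siRNA-NC replicate 3. The call of A_23_P106194 was lost when any si-PPT1 array was left out, with limma adjusted p from 0.0521 to 0.0582. Its bound was then 2.78-fold to 2.93-fold, and the SE of its log2 difference 0.33, against 0.26 with all arrays. Of the falls, A_24_P691826 went from 6.25 ± 0.32 to 3.47 ± 0.30 (SD, n = 3 each), a difference of -2.79 log2 units (SE 0.23, 6.89-fold; limma adjusted p = 0.00884). A_23_P76386 went from 7.26 ± 0.10 to 4.48 ± 0.25 (SD, n = 3 each), a difference of -2.78 log2 units (SE 0.15, 6.88-fold; limma adjusted p = 0.00435). The genes and genome positions of these 4 probes were not analysed here. Of the 10 rises that the rule ranked highest, 2 exceeded that limit on all 6 arrays (2.52 and 2.64 log2 units), and of the 10 falls 7 did (2.38 to 2.79 log2 units down). These shares are not comparable, since falls have their low values on si-PPT1 arrays, where the limit was 2.12 to 3.23. The mean levels of both named falls after si-PPT1, 3.47 and 4.48, would lie below the limits of siRNA-NC replicates 2 and 3.

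**Figure D2:**
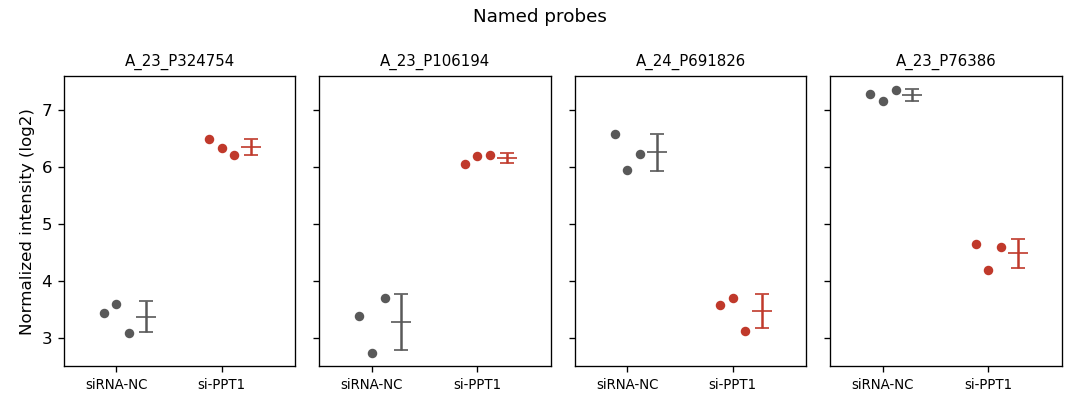
Normalized intensity (log2) of the 4 named probes on each array, siRNA-NC in grey and si-PPT1 in red, with the group mean and SD (n = 3) beside the points. The rule that picked the probes required groups that do not overlap. The control values of the 2 rises on siRNA-NC replicates 2 and 3 are not above the 95th percentile of the ERCC and ETG control probes.

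Calls were concentrated in bright probes. Of the 12250 bright probes 2135 were called (17.4%), 986 higher and 1149 lower, against 970 of the 45951 dimmer probes (2.11%). The median SD within groups was 0.05 below log2 1.5, where 15 of 14591 probes were called, 0.78 at log2 2 to 3 and 0.06 above log2 11. Within siRNA-NC the median SD at log2 2 to 3 was 0.92, and within si-PPT1 0.40. Among called probes between log2 2 and 3, 67 were higher and 7 lower. Between log2 9 and 11, 322 were higher and 440 lower. The balance did not follow the level throughout. It was 124 higher and 101 lower at log2 1.5 to 2, 185 and 163 at log2 11 to 13, and 46 and 23 above log2 13. When only the bright probes were tested, a choice made after seeing the data, 5137 of 12250 were called by limma, 2487 higher and 2650 lower.

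The criterion of the design text selected 932 probes, more than the 476 that limma called at least 2-fold. By the methods' t-test, unadjusted p under 0.05 with a fold above 2, 679 probes were higher and 253 lower. The 932 included all 476, and 745 of its members lay below log2 7, a share similar to that of all probes (45951 of 58201). Without siRNA-NC replicate 1 the number higher was 1351, and without siRNA-NC replicate 3 it was 417. After Benjamini-Hochberg adjustment the methods' t-test kept 174 probes higher and 169 lower at that fold. Without a fold limit it had 9613 probes at an unadjusted p under 0.05 and 2698 after adjustment.

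The control probes also differed between arrays. The mean of 7 spike-in probes in the measurable range was 11.15 ± 0.05 (SD, n = 3) after si-PPT1 and 11.29 ± 0.04 (SD, n = 3) after siRNA-NC. This difference of -0.15 log2 units had an exact two-sided permutation p of 0.1, the smallest that 3 arrays against 3 can give. Of the 7 probes, 6 were lower after si-PPT1, and in 4 of them the groups did not overlap. The differences of the 7 ran from -0.26 to 0.03 log2 units. At the dim end, siRNA-NC replicates 2 and 3 stood apart from the other 4 arrays. On siRNA-NC replicate 3, 2143 probes lay over 2 log2 units above all other arrays, and on siRNA-NC replicate 2, 740. On each of the other 4 arrays this number was 18 to 73. Over 2 log2 units below all other arrays lay 195 probes on siRNA-NC replicate 3 and 6 on siRNA-NC replicate 2. On each of the other 4 arrays 0 probes did.

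**Figure D3:**
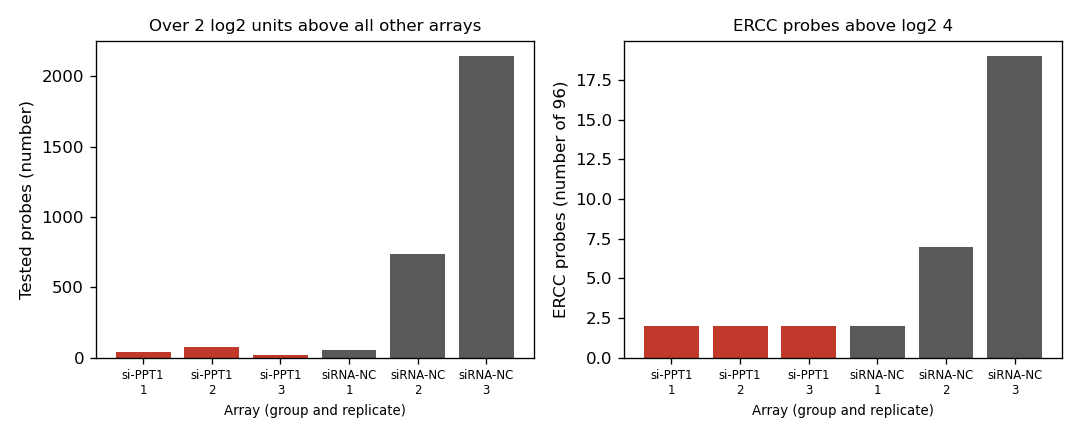
Left, number of tested probes on each array that lie over 2 log2 units above all 5 other arrays. Right, number of the 96 ERCC control probes above log2 4; si-PPT1 arrays are red and siRNA-NC arrays grey, and siRNA-NC replicate 3 is highest in both panels (2143 tested probes and 19 ERCC probes).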

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

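All tests in this part were chosen after the results were seen. Both results below are signals in control probes that were not themselves compared between the groups, above the middle value of the 3 siRNA-NC arrays. On siRNA-NC replicate 3, 19 of the 96 ERCC probes exceeded log2 4, against 7 on siRNA-NC replicate 2 and 2 on each other array. On siRNA-NC replicate 2, the dark corner control read log2 4.99, against 1.25 to 1.605 on the other 5 arrays.

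The raised ERCC probes on siRNA-NC replicate 3 went with raised gene probes. Among gene probes at or below log2 4 on all other arrays, 2095 of 33416 (6.27%) lay over 2 log2 units above them on this array. Transcripts of the cells as the whole source are argued against by the ERCC probes, which are made for synthetic RNA controls: 16 of 89 such dim probes (17.98%, exact 95% interval 10.6 to 27.6) were raised in the same way, against a limit of 1% that was set after these probes had been seen. Background signal on the array stays open: it was tested on the same ERCC probes, which had raised the question, and the dark corner control read only log2 1.605 there. On siRNA-NC replicate 2, where the dark corner control was raised, 736 of 31934 gene probes at or below log2 4 on all other arrays (2.305%) were raised in the same way. So were 5 of 77 such ERCC probes (6.494%, exact 95% interval 2.14 to 14.5). What raised the probes on either array, on the slide or in the authors' processing, was not determined.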

How the results depend on the processing

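The named probes were chosen for large changes, so their kept direction is no test, and the filters, the trended prior, the methods' t-test and the replicate block leave their differences as they are by construction. Over the 18 alternatives run on each, A_23_P106194 lost its call in 5 and the other 3 in 2 each. With each array left out in turn, the bounds on the 2 named rises ran from 2.08-fold to 4.61-fold (A_23_P324754, 3.19-fold with all arrays) and from 1.83-fold to 4.11-fold (A_23_P106194, 2.83-fold with all arrays). Centring on the median or 75th percentile, a second quantile normalization, the filter at the median level and the trended prior left every limma count within 1.5 times of the reported one. The filter at the 25th percentile gave 1797 calls (894 higher, 903 lower), and the cause was not tested. Array weights gave 5386 calls (2964 higher, 2422 lower, 529 higher at least 2-fold), and the cause was not tested. The methods' t-test with Benjamini-Hochberg adjustment gave 174 probes higher at least 2-fold. Of 19 alternatives in all, 10 kept the number called within 1.5 times, 7 gave fewer and 2 gave more.

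The 4 alternatives added after seeing the data gave the following. Centring on spike-in probes gave 2662 higher and 696 lower, 492 and 117 at least 2-fold, and 1117 and 151 by the methods' t-test, by its construction, which moves all probes of an array alike. Keeping probes above the array's own limit on all 3 arrays of either group gave 2535 higher and 2103 lower. By the methods' t-test it gave 437 higher and 188 lower. The limits were 2.12 to 3.23 on si-PPT1 arrays but 4.84 and 5.73 on siRNA-NC replicates 2 and 3. Dim probes therefore enter more easily when they are high after si-PPT1, so this balance of rises and falls is no result. Keeping probes above log2 7 gave 5137 calls, 2487 higher and 2650 lower, 79 and 109 at least 2-fold, and 78 and 109 by the methods' t-test, with fewer probes tested. Without siRNA-NC arrays 2 and 3 there were 19 calls, 0 higher and 19 lower, all at least 2-fold, and 0 of the 3105 reported calls were among them. In that fit the lone control array is assumed to vary like the si-PPT1 arrays. All 3105 kept their direction, which is no test, since the groups did not overlap in any called probe. Of the named falls, A_24_P691826 differed by -3.11 log2 units (against -2.79) and A_23_P76386 by -2.80 (against -2.78).

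Leaving out each array in turn gave 452 to 4639 calls, 199 to 1924 higher, 253 to 2715 lower, 101 to 674 higher at least 2-fold, and 417 to 1351 higher by the methods' t-test. Fewer arrays leave fewer residual degrees of freedom, which lowers counts by construction, but the rise without siRNA-NC replicate 1 was not explained by a test. Over bright probes the correlations of deviations from the group means were -0.16, 0.04 and 0.06 for same-numbered arrays 1, 2 and 3. For differently numbered arrays they ran from -0.17 to 0.163. Deviations from a mean of 3 arrays depend on each other, so these values cannot exclude a pairing by number. With the number as a replicate block, limma called 0 probes, 0 higher and 0 lower, with 8378 at an unadjusted p under 0.05 and a smallest adjusted p of 0.139. The planned tests of PPT1, of counts per gene, of mean probes per gene and of gene lists were not run, since probes were not paired with genes. The alternatives for linear values or scanner flags did not apply.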

Other observations

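All tests in this part were chosen after the results were seen, except the count of other splits of the arrays. The largest differences of group means did not pass the test. In 17 probes the means differed by more than in any called probe (over 2.97 log2 units), 7 higher and 10 lower after si-PPT1. In all 17 a single array lay at least 7.15 log2 units from the other 5, and the lowest limma adjusted p was 0.528. The single array was si-PPT1 replicate 2 for 7 probes, siRNA-NC replicate 1 for 5 and siRNA-NC replicate 2 for 5. A ranking by fold alone would put these probes first.

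Probe name series, the number after A_ in the names, differed in how often they were called. What the series stand for is not given in the sources used here. Of the 11821 probes of the A_23 series 11.1% were called, 633 higher and 682 lower. Of the 12263 probes of the A_22 series 1.68% were called, 136 higher and 70 lower. The A_22 probes were dimmer, with a median level of log2 1.71 against 6.47. Within 11 bins of signal level the common odds ratio of a call, A_22 against A_23, was 0.513 (95% interval 0.427 to 0.615), with probes treated as independent, which they are not.

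In the comparison of all 6 arrays, 417 of the called probes between log2 3 and 7 were higher after si-PPT1 and 239 lower (63.6% higher). The balance of all probes in this range, called or not, was not computed. Over all probes above the median level the median difference was 0.074 log2 units, against -0.009 above log2 7. The excess of rises may therefore not be particular to called probes. Both the signal of siRNA-NC replicate 3 and an effect of si-PPT1 on weakly expressed genes stay open as explanations. Without that array 56.9% were higher (exact 95% interval 53 to 60.7, probes treated as independent). Leaving out other single arrays moved the share between 40.9% (without si-PPT1 replicate 3, interval 32.3 to 50.02) and 77.1% (without siRNA-NC replicate 1). This spread between arrays covers an even balance, so the explanations cannot be told apart.

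The spike-in probes read lower after si-PPT1 by -0.147 log2 units, with all 3 si-PPT1 arrays (11.1 to 11.2) below all 3 siRNA-NC arrays (11.3). A smaller amount of spike-in RNA and a larger amount of labelled mRNA per total RNA would both lower this mean. These cannot be told apart, since each would shift all spike-in transcripts alike and the number of arrays allows no p under 0.1. The single probes did not shift alike, with differences from -0.26 to 0.03 log2 units, and the cause of this spread was not tested.

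With 10 splits of the 6 arrays into 3 and 3, no share under 0.05 can be reached. The real split called 3105 probes and was the only 1 of the 10 to reach that number, and the highest of the other splits called 0 by limma, with 682 to 2563 probes at an unadjusted p under 0.05 against 9858 in the real split. Every other split mixes the groups, so a difference between the groups widens its spread and lowers its counts. The counts of the other splits therefore do not show what chance alone would give.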
